A study of Mus musculus with 11 samples.

How the data were processed

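RNA of mouse B16F10 melanoma cells was sequenced in 11 libraries of 3 lines: a Cas9 control line and 2 clones with a knockout of Ung, ΔUNG and ΔUNG_2. Cells had received DMSO or 5 µM of the ATR inhibitor AZD6738 (ATRi) for 48 h, per the labels. Groups were taken from the sample titles. Of the 6 groups, 5 held 2 libraries and the ΔUNG_2 ATRi group held 1. The titles call the libraries biological replicates, and nothing used here says whether they came from separate passages or days, so p-values measure the spread between these libraries.

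Expression values are FPKM (fragments scaled by gene length and sequencing depth), as deposited by the authors, 1 column per library. Per the submitters' processing notes, HISAT2 was used. Its version, the counting tool, the annotation release and the genome build are not given in the sources used here. Library preparation and sequencing were done by Novogene, per the labels' protocols. The deposited read table also gives the percent of bases with a quality of at least Q30 and the percent of G and C per library; both were used only to describe the libraries. That table holds 1 library that is not among the samples analysed here, and its row was not used.

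Each FPKM value multiplied by the deposited gene length was a whole multiple of 1 step per library, within a tolerance of 0.01, for 100% of values in every library. This gave back the fragments per gene. The fragments behind the FPKM numbered 17014697 to 28464757 per library, and the deepest were both Cas9 control ATRi libraries. A value of 0 allows up to 3 fragments, which for a gene of 1 kb is 0.105 to 0.176 FPKM; this limit covers counting error only. Of 14528 listed genes, 13994 had the same chromosome, start and end in GENCODE mouse M21, which was used only to repair 19 symbols that a spreadsheet had turned into dates and for GC content. Coordinates are those of the deposited table.

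The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5) for the 11323 genes with a mean of at least 0.5 FPKM over all libraries. The model had 1 mean per group over all 11 libraries, which left 5 residual degrees of freedom, with empirical Bayes moderation and an intensity trend. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested within a comparison, with a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. Errors of fold changes are standard errors (SE) and those of FPKM are standard deviations (SD). The lone ΔUNG_2 ATRi library was assumed to vary like the other groups.

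Gene lists, 27 in number, were tested with limma camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. A list's value is the median log2 fold change of its tested members. Estimated correlations and fry, a rotation test of a list against no change, were the alternatives. Counts adjusted over the list alone use only the p-values of the list's members.

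Genes were named by a rule: Ung; a panel of 14 genes, of which 13 were tested (Ifnb1 was not analysed here); per comparison up to 5 rises and 5 falls with the largest fold among genes past the threshold, with a mean of at least 1 FPKM and no overlap between the groups' libraries, leaving out predicted genes and pseudogenes; and the members of a list with the smallest adjusted p. Some genes named by this rule are not reported here. Genes common to both clones were ranked by the smaller of both folds. Cgas and Sting1 are listed under the older symbols Mb21d1 and Tmem173, and Rigi as Ddx58. The design, the lists, the rule and the other settings listed next were set before the data were examined.

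These settings were pseudocounts of 0.1 and 1, no filter and a filter at 2 FPKM, rescaling to the same FPKM sum or by median ratios, no intensity trend, only the groups compared, a block for the replicate number, a minimum fold, and leaving out each library in turn. Chosen after seeing the data were limma-voom on the fragments, thinning to the smallest depth, leaving out genes of under 200 bases, setting each clone against a different control DMSO library, and leaving out chromosome 12 with chromosome 8 from 80 Mb.

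The procedure was tested on simulated data with 200 changed genes. In the comparison of ΔUNG with the control under DMSO, over 11218 genes, limma recovered 61.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 98.5% of those changed 4-fold. For the difference in ATRi response of ΔUNG, over 11225 genes, it recovered 23.9%, 70.1% and 95.5%. In these 2 comparisons it also called 5 and 10 unchanged genes. For the difference in ATRi response of ΔUNG_2, with its single ATRi library, it recovered 25.4%, 56.7% and 87.9%. Null values for comparisons that share control libraries came from 100 simulations, in which each gene varied independently of the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.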

Results

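The series asks how loss of uracil-DNA glycosylase (UNG), the base excision repair enzyme that removes uracil from DNA, relates to inflammatory signalling within tumour cells. B16F10 is a mouse melanoma line, and AZD6738 inhibits ATR, a kinase of the replication stress checkpoint. Libraries held 45692790 to 74973328 clean reads, with 92.4% to 94.0% of bases at Q30. Replicates differed by more than counting noise in each of the 5 groups with 2 libraries, with a chi-square per degree of freedom of 4.73 to 27.6, so none was counted as a duplicate. The first principal component held 54.3% of the variance and the next 17.2%.

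Ung, on chromosome 5 from 114130386 to 114139323, had 2.86 and 2.48 FPKM in the Cas9 control DMSO libraries, 1.39 and 0.774 in ΔUNG DMSO, and 2.01 and 1.78 in ΔUNG_2 DMSO. Under ATRi it had 2.557 and 2.999 FPKM in the control, 1.27 and 0.675 in ΔUNG and 1.74 in the single ΔUNG_2 library. Ung was lower in ΔUNG than in the control under DMSO (log2 fold change -1.03 ± 0.23 SE, limma adjusted p = 0.0246). The value for ΔUNG_2 was -0.40 ± 0.23, adjusted p = 0.355. The ΔUNG call was lost without Cas9 control DMSO replicate 1 (-0.94, adjusted p = 0.142), without Cas9 control DMSO replicate 2 (-1.11, adjusted p = 0.0852), and without ΔUNG DMSO replicate 2 (-0.74, adjusted p = 0.125). Over these and the other settings its adjusted p ranged from 0.00248 to 0.142. Under ATRi, Ung had -1.18 ± 0.23 in ΔUNG (adjusted p = 0.0173; 0.0596 and 0.0738 without Cas9 control ATRi replicate 1 or 2, and 0.120 without ΔUNG ATRi replicate 2) and -0.54 ± 0.28 in ΔUNG_2 (adjusted p = 0.296). RNA level does not measure the protein, so the value in ΔUNG_2 neither supports nor contradicts its label.

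**Figure D1:**
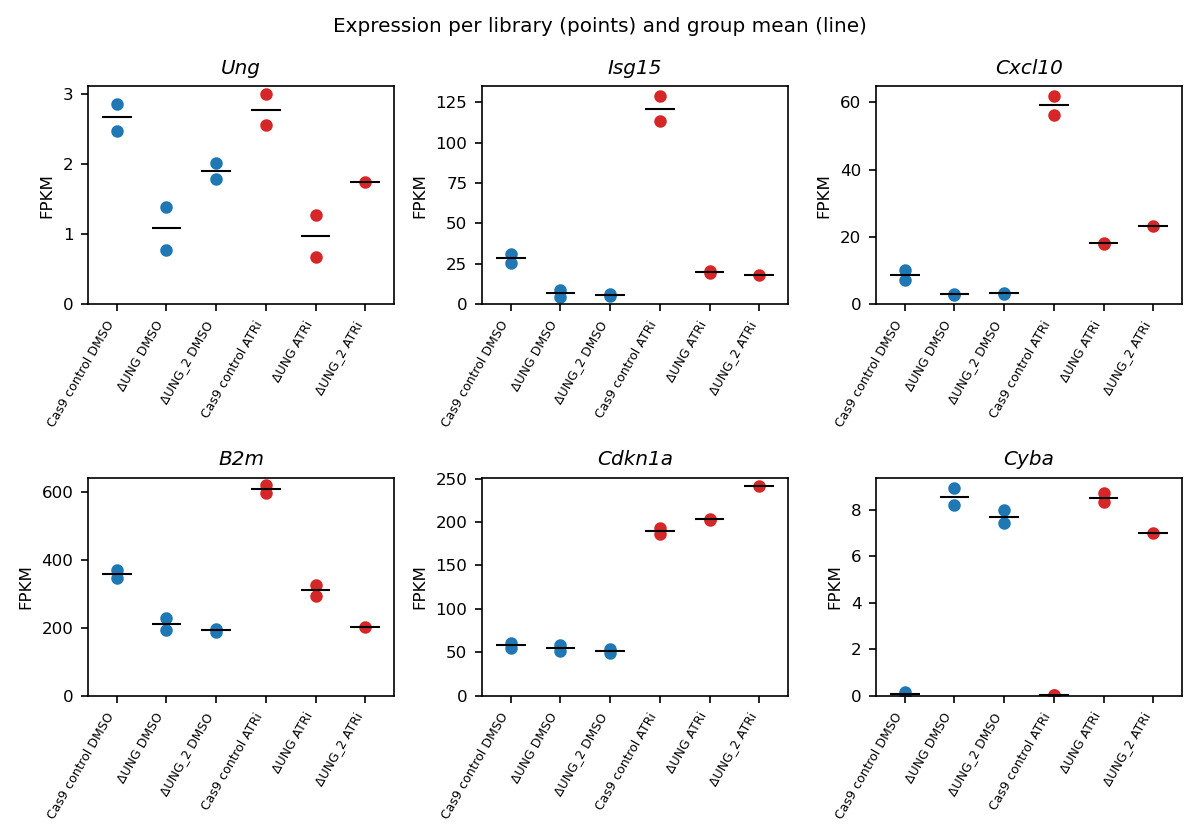
FPKM of Ung, Isg15, Cxcl10, B2m, Cdkn1a and Cyba per library (points; blue DMSO, red ATRi) with group means (lines), on linear axes that start at 0. Isg15 averaged 28.4 FPKM in the control under DMSO and 121 under ATRi, and stayed at or under 19.9 in the group means of the clones.

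The first comparison asks how the clones differ from the control without ATRi. Genes induced by type I interferon were lower in both clones. Isg15, a ubiquitin-like interferon-induced protein, had 28.4 ± 3.69 FPKM (SD, n = 2) in the control, 6.80 ± 3.24 in ΔUNG and 5.86 ± 0.838 in ΔUNG_2. Trim30a, an interferon-induced regulator, fell by 2.91 on the log2 scale in ΔUNG and by 3.62 in ΔUNG_2. Of 45 tested interferon-stimulated genes, 35 fell in ΔUNG and 40 in ΔUNG_2; adjusted over the list alone, 42 and 44 fell. The list's medians were -1.12 and -1.39, with limma camera adjusted p = 3.35e-37 and 5.57e-45. With an estimated correlation the calls were lost (adjusted p = 0.132 in ΔUNG and 0.0768 in ΔUNG_2).

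Among the other genes with the largest falls in both clones, Ddx58 (RIG-I, a sensor of viral RNA) fell by 2.16 in ΔUNG and by 2.40 in ΔUNG_2, with adjusted p = 8.50e-05 and 4.02e-05. Oas1a, an oligoadenylate synthetase gene, fell by 2.09 and by 2.48, and Rtp4 fell by 2.07 and by 2.33. Usp18, which restrains interferon receptor signalling, fell by 1.98 in ΔUNG and by 2.24 in ΔUNG_2. Within the panel, Ifit1 had log2 fold changes of -1.56 and -2.00, Cxcl10 of -1.37 and -1.29, Ccl5 of -1.02 and -0.99, Irf7 of -0.74 and -0.92 and Mdm2 of -0.40 and -0.41, each past the threshold. The Irf7 call in ΔUNG was lost without Cas9 control DMSO replicate 1 (-0.66, adjusted p = 0.219) or replicate 2 (-0.83, adjusted p = 0.123) and without ΔUNG DMSO replicate 2 (-0.54, adjusted p = 0.183). The Irf7 call in ΔUNG_2 and both Mdm2 calls were lost without either DMSO replicate of the control or of the clone; adjusted p was then 0.0685 to 0.130 for Irf7, and 0.0534 to 0.123 and 0.0736 to 0.114 for Mdm2. Mb21d1 (cGAS) had 0.09 and 0.14, Tmem173 (STING) 0.07 and 0.09, Ifnar1 0.15 and 0.12, H2-K1 0.30 and 0.05 and Cdkn1a -0.08 and -0.17, none of which passed.

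Lists next to the interferon response were lower too. Of 8 interferon-gamma-inducible GTPases and regulators, 6 fell in each clone, among them the guanylate-binding protein gene Gbp3 (-1.69 ± 0.15 and -1.77 ± 0.15). Of 16 genes of MHC class I antigen presentation, 4 fell and 1 rose in ΔUNG, and 6 fell in ΔUNG_2. B2m, the light chain of MHC class I, had 358 ± 16.9 FPKM in the control, 211 ± 26.0 in ΔUNG and 192 ± 7.66 in ΔUNG_2 (SD, n = 2). Of 20 cytokine, chemokine and NF-kB genes, 5 fell in ΔUNG and 6 in ΔUNG_2. The camera calls of these 3 lists had adjusted p between 1.59e-08 and 0.0431 and were lost with an estimated correlation (adjusted p = 0.114, 0.246 and 0.15 in ΔUNG, and 0.0768 for each in ΔUNG_2). The median of MHC class I in ΔUNG, -0.13, was also no longer called without Cas9 control DMSO replicate 1 (-0.121, adjusted p = 0.0853) or ΔUNG DMSO replicate 2 (-0.108, adjusted p = 0.0982), and was -0.247 without Cas9 control DMSO replicate 2.

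Of 24 pigmentation genes tested, 13 rose in ΔUNG, and 8 rose and 1 fell in ΔUNG_2, with medians of 0.33 and 0.18 (camera adjusted p = 5.20e-07 and 0.000521; 0.354 and 0.624 with an estimated correlation). Trpm1, a melanocyte cation channel, rose by 1.98 ± 0.12 in ΔUNG and 1.47 ± 0.12 in ΔUNG_2, and Mlph, a melanosome transport adaptor, by 0.75 ± 0.06 and 0.77 ± 0.06. Chaperones of the unfolded protein response gave 4 rises among 15 genes in each clone, among them Dnajc3 (0.59 and 0.44) and Herpud1 (0.80 and 0.70); Herpud1 in ΔUNG_2 had adjusted p = 0.0510 without ΔUNG_2 DMSO replicate 1. Of 27 glycolysis and hypoxia genes, 10 rose and 1 fell in ΔUNG, and 4 rose and 1 fell in ΔUNG_2; Car9, a hypoxia-induced carbonic anhydrase, rose by 2.31 ± 0.27 and 1.68 ± 0.27, while the enolase gene Eno2 fell by 1.13 and by 1.35. With an estimated correlation, adjusted p for the chaperones was 0.173 in ΔUNG and 0.506 in ΔUNG_2, and for glycolysis and hypoxia 0.530 and 0.629. The chaperone median was 0.28 in ΔUNG (0.181 without Cas9 control DMSO replicate 1 and 0.182 without ΔUNG DMSO replicate 2) and 0.05 in ΔUNG_2, where it was 0.101 without Cas9 control DMSO replicate 2, 0.006 (adjusted p = 0.248) without replicate 1 of that group and -0.08 after rescaling to the same FPKM sum. The glycolysis and hypoxia median was 0.38 in ΔUNG (0.196 without Cas9 control DMSO replicate 1) and 0.21 in ΔUNG_2, with 0.055 (adjusted p = 0.545) without Cas9 control DMSO replicate 1 and 0.389 without replicate 2.

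Outside the lists, Cyba, the p22phox subunit of NADPH oxidases on chromosome 8 from 122424776 to 122432930, was at 0.0788 ± 0.112 FPKM in the control, 8.57 ± 0.526 in ΔUNG and 7.70 ± 0.399 in ΔUNG_2 (SD, n = 2). Mbp, known as a myelin protein gene, rose from 5.35 ± 0.114 FPKM to 49.2 ± 2.19 and 70.1 ± 0.875. Il17b, a cytokine gene, rose by 2.10 ± 0.36 in ΔUNG and 1.79 ± 0.36 in ΔUNG_2; these were 1.40 and 1.09 without Cas9 control DMSO replicate 2. The Il17b call in ΔUNG was lost without ΔUNG DMSO replicate 1 (adjusted p = 0.0536), and that in ΔUNG_2 without ΔUNG_2 DMSO replicate 1 (adjusted p = 0.0814) or 2 (adjusted p = 0.103).

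By limma, 619 genes were higher and 368 lower in ΔUNG, and 506 were higher and 422 lower in ΔUNG_2. The total of 987 in ΔUNG was 370 and 405 without Cas9 control DMSO replicate 1 or 2, and 570 and 531 without ΔUNG DMSO replicate 1 or 2. The total of 928 in ΔUNG_2 was 391 and 389 without those control libraries, and 317 and 289 without ΔUNG_2 DMSO replicate 1 or 2. Rescaling to the same FPKM sum, 10.3% to 26.3% of which came from the 57-base gene Gm23935, moved the median of all genes to -0.11 and -0.13 and gave 137 higher and 186 lower genes in ΔUNG and 114 and 267 in ΔUNG_2. In both clones together, 390 genes were higher and 252 lower, against 27.7 and 13.7 for independent lists. The 642 shared genes were 264 and 280 without Cas9 control DMSO replicate 1 or 2, 261 and 250 without ΔUNG_2 DMSO replicate 1 or 2, 411 without ΔUNG DMSO replicate 2, and after rescaling to the same FPKM sum 79 higher and 144 lower. Fold changes of both clones correlated across genes, which are not independent replicates, at r = 0.81, against 0.50 in simulations of unchanged clones that share the controls, with a covariance of 0.080 against 0.012. In these 100 simulations, at most 1 gene was called in both clones. Genes were simulated as independent, while real genes can vary together, with an estimated correlation of 0.40 among the interferon-stimulated genes. The simulated values can therefore understate the spread. Part of the excess over independent lists may come from the shared control libraries. With each clone set against a different one of the 2 control libraries, which was chosen after seeing the data, 122 genes were higher and 86 lower in both clones, against 5.5 and 1.9 for independent lists, with a covariance of 0.067. With the control libraries exchanged, 138 were higher and 82 lower, against 5.3 and 1.6, with a covariance of 0.068. In the ATRi libraries, which share no library with these, 332 of the 390 and 205 of the 252 genes had the same sign in both clones, against 103 to 144 and 65 to 95 in 100 simulations, chosen after seeing the data, of clones unchanged under ATRi that share its control libraries. Of these genes, 103 and 89 were called in both clones under ATRi. The simulations of the ATRi libraries also took genes as independent, so their ranges can be too narrow. The ATRi libraries come from the same lines, so any lasting difference between the control line and the clones would carry over to them. Whether the clones share an origin apart from the control line was not tested. The agreement between the clones therefore does not tell loss of UNG from clonal origin.

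The clones differed from each other in 5 genes under DMSO, while 684 had an unadjusted p under 0.05. Without any difference, a share of 0.05 of the 11323 genes tested would also be under that limit. The count of 684 was not tested against that share. Pla2g2e (-0.88 ± 0.09), Armcx1 (-0.86 ± 0.11) and Smg9 (-0.80 ± 0.08) were lower in ΔUNG_2 than in ΔUNG, and Gm43549 (0.97 ± 0.09) and Pcdhgb1 (1.46 ± 0.19), named after their values were seen, were higher. Pcdhgb1 shares exons with its neighbours, so its value is uncertain. The count was 1 without ΔUNG_2 DMSO replicate 1; without ΔUNG_2 DMSO replicate 2 or ΔUNG DMSO replicate 1 limma called 0. The calls of Pla2g2e and Smg9 were lost without each of these 3 libraries (adjusted p = 0.106 to 0.196 and 0.0737 to 0.113), and that of Armcx1 also without ΔUNG DMSO replicate 2 (adjusted p = 0.148 to 0.371). limma-voom gave 11 genes. Lists that camera called lower in ΔUNG_2 than in ΔUNG included the interferon-stimulated genes (median -0.24, adjusted p = 2.47e-10; 0.349 with an estimated correlation), cholesterol synthesis (-0.18, adjusted p = 2.47e-10; 0.102 with an estimated correlation) and NRF2 targets (-0.20, adjusted p = 1.60e-06; 0.166 with an estimated correlation). The interferon-stimulated genes were at -0.15 (adjusted p = 0.0845) without ΔUNG DMSO replicate 1 and at -0.40 without ΔUNG DMSO replicate 2; among them Ifit3 had -0.56 ± 0.12 (adjusted p = 0.353). Panel genes had values from -0.43 (Ifit1) to 0.09 (Cxcl10), and Ung had 0.63 ± 0.23 (adjusted p = 0.760).

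**Figure D2:**
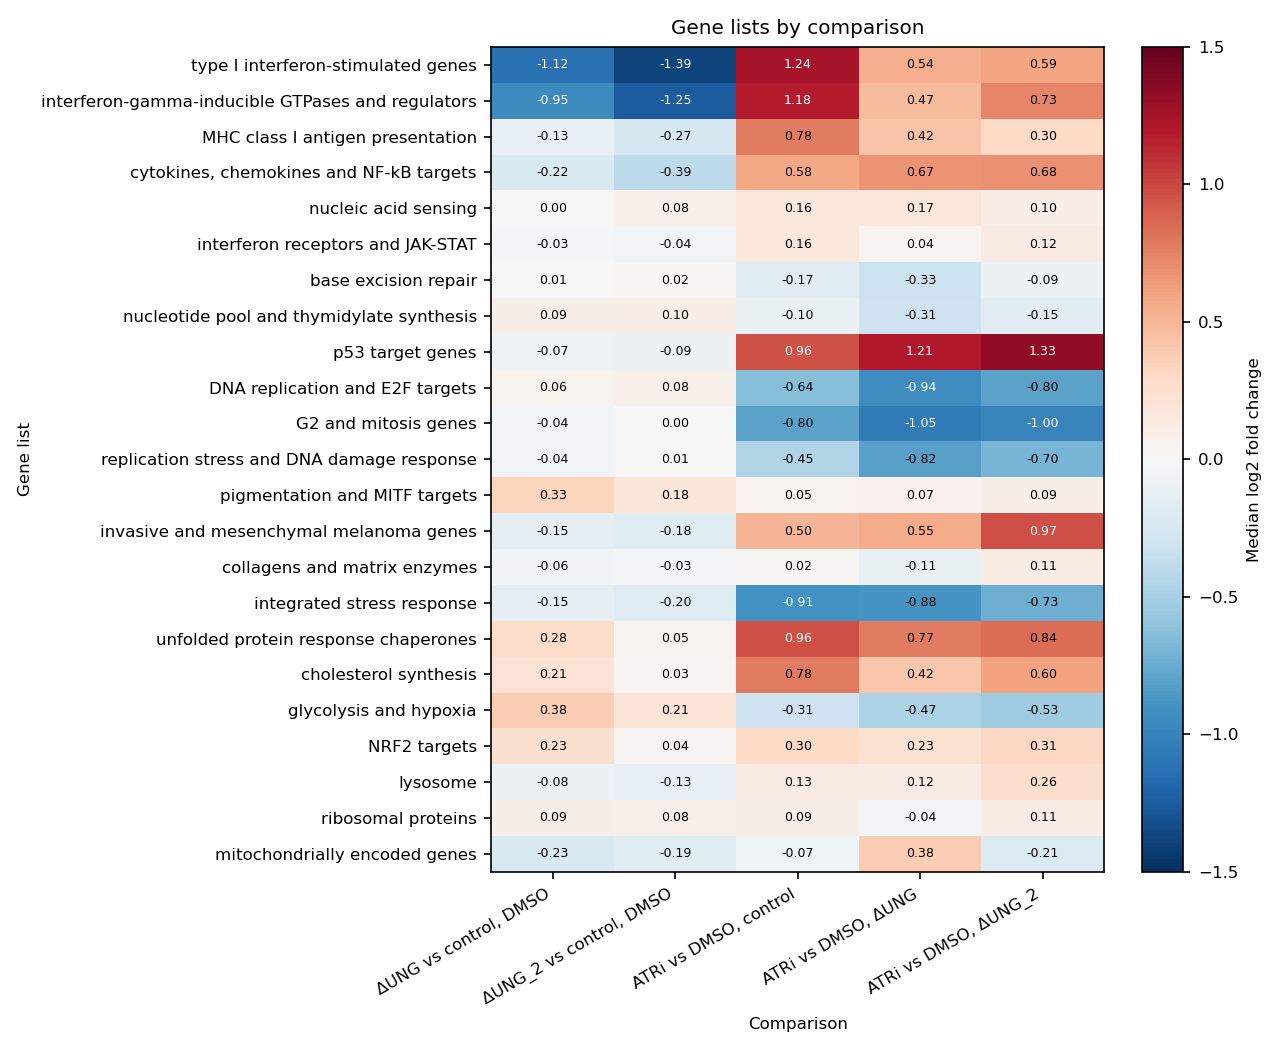
Median log2 fold change of the tested members of each gene list with at least 5 tested members (rows) in 5 comparisons (columns); red is higher and blue lower, and the number in each cell is the median. The interferon-stimulated genes read -1.12 and -1.39 in the clones under DMSO and 1.24 with ATRi in the control.

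The next comparison asks what ATRi did in the control line. Interferon-stimulated genes rose: 43 of 45 passed and 45 passed when adjusted over the list alone, with a median of 1.24 (limma camera adjusted p = 6.86e-23; adjusted p = 0.108 with an estimated correlation). Isg15 rose to 113 and 129 FPKM in the ATRi libraries. Cxcl10, a T cell attracting chemokine, rose by 2.72 ± 0.14, Ifit3b by 2.58 ± 0.12, Ifit1 by 2.02 ± 0.14, Ccl5 by 1.77 ± 0.15 and Irf7 by 1.52 ± 0.19. Reads of Ifit3b, Oas1a, Trim30a, Trim12c and H2-K1 can come from near-identical relatives, so their values are uncertain. All 8 interferon-gamma-inducible genes and 14 of 16 MHC class I genes rose, including B2m (0.77 ± 0.09), Tap1 (1.71 ± 0.18) and H2-K1 (1.24 ± 0.21); with an estimated correlation their adjusted p was 0.0493 and 0.0256. Tmem173 rose by 0.57 ± 0.08, while Mb21d1 (-0.05 ± 0.11), Ifnar1 (0.09 ± 0.06) and Ung (0.05 ± 0.23) did not pass.

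Genes of cell division fell and p53 targets rose. Of 38 G2 and mitosis genes, 37 fell (median -0.80), among them the spindle motor gene Kif11 (-1.06 ± 0.08) and Ect2 (-1.03 ± 0.08). Of 40 DNA replication and E2F targets, 35 fell (median -0.64), among them Rfc4, a subunit of the clamp loader (-1.06 ± 0.07), and the helicase subunit gene Mcm2 (-0.85 ± 0.08). In the list of replication stress and DNA damage response, 30 of 38 fell, including Rad51c, Fancd2 and Chek1. Of 32 p53 target genes, 26 rose (median 0.96), led by Cdkn1a, the p21 cell cycle inhibitor (1.70 ± 0.08), Dcxr (1.69 ± 0.08) and Btg2 (2.37 ± 0.13), with Mdm2 at 0.92 ± 0.08. The p53 call held with an estimated correlation (adjusted p = 0.0202), and those of mitosis (adjusted p = 0.110), replication (adjusted p = 0.115) and damage response (adjusted p = 0.108) did not.

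Stress programmes moved in opposite directions. Integrated stress response genes fell in 17 of 21 cases, led by Nupr1 (-2.58 ± 0.10), Trib3 (-2.40 ± 0.14) and the folate enzyme gene Aldh1l2 (-1.91 ± 0.11). Unfolded protein response chaperones rose in 13 of 15 cases, with Hspa5, the main chaperone of the endoplasmic reticulum, at 1.43 ± 0.08. Cholesterol synthesis genes rose in 18 of 22 cases, including Insig1 (1.34 ± 0.07). NRF2 targets gave 11 rises and 1 fall among 18, with the sulfiredoxin gene Srxn1 at 1.27 ± 0.08. With an estimated correlation, adjusted p was 0.114 for the stress response, 0.0634 for the chaperones, 0.0261 for cholesterol synthesis and 0.108 for NRF2 targets.

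Besides Cxcl10 and Ifit3b, the large single rises included Egr1, an immediate early transcription factor (3.01 ± 0.20), Usp17le (2.96 ± 0.17) and Dhrs3, a retinol dehydrogenase gene (2.58 ± 0.22). Usp17le has near-identical copies, so its value is uncertain. Akr1b7 (-2.00 ± 0.39), Platr16 (-1.92 ± 0.40) and n-R5s204 (-2.11 ± 0.44), a gene of 119 bases, were among the falls. In all, 1900 genes were higher and 1905 lower. Without Cas9 control DMSO replicate 1 the total of 3805 was 2430, without replicate 2 of that group it was 2197, and after rescaling to the same FPKM sum it was 2002.

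In ΔUNG, ATRi raised 1863 genes and lowered 2196, and in ΔUNG_2, with 1 ATRi library, 2044 and 1961. Calls were shared by all 3 lines for 1110 higher and 1103 lower genes. Cdkn1a rose by 1.87 ± 0.08 in ΔUNG and 2.21 ± 0.10 in ΔUNG_2, Mdm2 by 1.36 ± 0.08 and 1.39 ± 0.10, and Egr1 by 3.49 ± 0.20 and 3.86 ± 0.24. All 40 replication and 38 mitosis genes fell in ΔUNG, and 37 of each in ΔUNG_2. Nupr1 fell by 2.99 and by 2.77. Further large rises were Csn3 in ΔUNG (3.21 ± 0.19) and Lif (3.40 ± 0.21), Cpz (3.31 ± 0.23) and Btg2 (3.14 ± 0.16) in ΔUNG_2. G0s2 (-2.73 ± 0.23), Car9 (-2.61 ± 0.27), Il17b (-2.35 ± 0.36) and Hist1h2af, 1 of several similar histone genes and therefore uncertain, fell in ΔUNG, and Slc16a3, a lactate transporter gene (-2.94 ± 0.33), Aire (-2.84 ± 0.33) and Platr16 in ΔUNG_2. Mir1943, Mir1957a and Mir23a, genes of 66 to 75 bases, were also called, on few fragments; Mir23a was lost in ΔUNG without either DMSO or either ATRi replicate of ΔUNG (adjusted p = 0.0530 to 0.148) and in ΔUNG_2 without ΔUNG_2 DMSO replicate 2 (adjusted p = 0.191). After rescaling to the same FPKM sum the totals of 4059 and 4005 were 2319 and 2022.

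Interferon-stimulated genes also rose in the clones: 28 rose and 1 fell in ΔUNG, and 22 rose and 1 fell in ΔUNG_2, with medians of 0.54 and 0.59 (limma camera adjusted p = 5.39e-09 and 7.01e-06; adjusted p = 0.282 and 0.447 with an estimated correlation). Isg15 rose by 1.56 ± 0.24 and 1.54 ± 0.30, Ifit1 by 1.47 ± 0.14 and 1.78 ± 0.18, Cxcl10 by 2.42 ± 0.14 and 2.69 ± 0.17, and Ccl5 by 1.72 ± 0.15 and 2.21 ± 0.18. B2m rose in ΔUNG (0.56 ± 0.09) and had 0.07 ± 0.12 in ΔUNG_2. H2-K1 had -0.06 ± 0.21 and 0.02 ± 0.26, neither past the threshold, and Ifnar1 had 0.10 ± 0.06 and 0.13 ± 0.08. Tmem173 rose by 0.49 ± 0.08 and 0.46 ± 0.10. Mb21d1 had -0.57 ± 0.11 (adjusted p = 0.00280) in ΔUNG and -0.21 ± 0.13 (adjusted p = 0.245) in ΔUNG_2. Irf7 had 0.42 ± 0.19 (adjusted p = 0.115) and 0.80 ± 0.24 (adjusted p = 0.0256), the latter 0.70 without ΔUNG_2 DMSO replicate 1 (adjusted p = 0.102).

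The test of the difference in response asks whether ATRi acted differently in the clones. Both clones are set against the same control libraries, so their values are not independent of each other. As a list, interferon-stimulated genes rose less in the clones, with median differences of -0.62 in ΔUNG and -0.66 in ΔUNG_2 (limma camera adjusted p = 2.53e-19 and 1.30e-21; adjusted p = 0.236 and 0.147 with an estimated correlation). Adjusted over the list alone, 27 and 22 of the 45 members passed; over all genes tested, Bst2 (tetherin) passed in ΔUNG_2, and the smallest adjusted p in ΔUNG was 0.0627 (Dhx58, -1.30). Bst2 went from 70.9 to 205 FPKM in the control and from 23.4 to 23.5 in ΔUNG_2 (-1.52 ± 0.20, adjusted p = 0.0372). Differences for Cxcl10 (-0.30 and -0.03), Ccl5 (-0.05 and 0.44), Isg15 (-0.52 and -0.53), Ifit1 (-0.55 and -0.24), Irf7 (-1.10 and -0.72), B2m (-0.21 and -0.69), H2-K1 (-1.31 and -1.22), Mb21d1 (-0.53 and -0.16), Cdkn1a (0.17 and 0.52) and Mdm2 (0.44 and 0.47) did not pass.

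Single genes with a different response were Hap1 (-1.21 ± 0.14) and Mvd, an enzyme of cholesterol synthesis (-1.13 ± 0.12), in ΔUNG. In ΔUNG_2, with 8 genes, Bst2, Slfn9 (-1.39 ± 0.15), Hap1 (-1.17 ± 0.15) and Rnf213 (-1.13 ± 0.14) were lower, and Dusp10 (1.20 ± 0.15), Dcxr (0.92 ± 0.12) and Mcam (0.77 ± 0.09) were among those higher. The unadjusted p was under 0.05 for 1524 and 1396 of 11323 genes, where a share of 0.05 would be under it without any difference. By limma-voom, 65 and 73 genes were called. Without Cas9 control DMSO replicate 1 or 2 the counts of 2 and 8 were 4 and 6 in ΔUNG and 1 and 0 in ΔUNG_2. Without Cas9 control ATRi replicate 1 or 2 they were 7 and 7 in ΔUNG and 0 and 10 in ΔUNG_2. Without ΔUNG DMSO replicate 1 or either ΔUNG ATRi replicate limma called 0 in ΔUNG, and without either ΔUNG_2 DMSO replicate 0 in ΔUNG_2. Hap1 and Mvd in ΔUNG were also lost without ΔUNG DMSO replicate 2 (adjusted p = 0.0720) and Cas9 control ATRi replicate 2 (adjusted p = 0.0509), and Hap1 without Cas9 control ATRi replicate 1 (adjusted p = 0.0666). In ΔUNG_2, Hap1 alone of the 8 passed without Cas9 control DMSO replicate 1, and without Cas9 control ATRi replicate 2 Bst2, Hap1, Dusp10 and Dcxr were among those lost (adjusted p = 0.0630).

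Under ATRi, the clones were lower than the control in 44 of 45 interferon-stimulated genes in ΔUNG and 43 in ΔUNG_2, with medians of -1.82 and -2.03 (limma camera adjusted p = 1.25e-57 and 5.79e-59; adjusted p = 0.0542 and 0.0516 with an estimated correlation). Trim30a fell by 4.08 and by 4.46, and the log2 fold changes were -2.96 and -3.41 for Usp18, -2.89 and -3.11 for Trim12c, and -2.83 and -3.13 for Igtp, an interferon-inducible GTPase gene. Oasl2 fell by 2.78 in ΔUNG and Bst2 by 3.10 in ΔUNG_2. B2m had -0.97 and -1.59, Isg15 -2.57 and -2.72, Ifit1 -2.11 and -2.24, Irf7 -1.84 and -1.64, Cxcl10 -1.67 and -1.32 and H2-K1 -1.01 and -1.17, each past the threshold. Ccl5 had -1.06 (adjusted p = 0.00290) and -0.55 (adjusted p = 0.109), and Mb21d1 -0.44 (adjusted p = 0.0433) and -0.02 (adjusted p = 0.929). Tmem173 (-0.01 and -0.01), Ifnar1 (0.17 and 0.16), Cdkn1a (0.10 and 0.35) and Mdm2 (0.04 and 0.06) did not pass. H2-K1 was lost in ΔUNG without either control or either ΔUNG ATRi replicate (adjusted p = 0.0654 to 0.142) and in ΔUNG_2 without Cas9 control ATRi replicate 1 (adjusted p = 0.113) or 2 (adjusted p = 0.0558). Mb21d1 was lost without Cas9 control ATRi replicate 1 (-0.34, adjusted p = 0.203) and without ΔUNG ATRi replicate 1 (adjusted p = 0.133) or 2 (adjusted p = 0.155).

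Cyba was at 0.0338 and 0.0352 FPKM in the control ATRi libraries, 8.53 ± 0.274 in ΔUNG and 7.001 in ΔUNG_2. Mbp (3.43 ± 0.10 and 4.33 ± 0.12) was higher, as were Trpm1 (1.84 ± 0.12) and Pla2g2e (1.73 ± 0.09) in ΔUNG and Hapln1 (1.74 ± 0.17) and Aldh1a3 (1.35 ± 0.18) in ΔUNG_2. Mir7052, a gene of 65 bases, had 2.58 ± 0.54 in ΔUNG_2 and 1.70 without Cas9 control ATRi replicate 1. Srp54b, which has near-identical copies and is uncertain, had 1.83 ± 0.43 in ΔUNG, 1.05 (adjusted p = 0.0863) without Cas9 control ATRi replicate 2, and adjusted p = 0.157 and 0.110 without ΔUNG ATRi replicate 1 or 2. In total 341 genes were higher and 354 lower in ΔUNG, and 310 and 257 in ΔUNG_2; after rescaling to the same FPKM sum these were 71 and 205, and 42 and 141. Without Cas9 control ATRi replicate 1 the totals of 695 and 567 were 329 and 272, without ΔUNG ATRi replicate 1 or 2 the first was 429 or 225, and limma-voom gave 1248 and 1129.

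Lists that camera did not call between clones and control under DMSO included base excision repair, with medians of 0.01 and 0.02 (limma camera adjusted p = 0.942 and 0.880), nucleic acid sensing (1 rise and 3 falls of 20 in ΔUNG, 1 and 2 in ΔUNG_2; camera adjusted p = 0.894 and 0.536) and G2 and mitosis genes, with medians of -0.04 and 0.00 (camera adjusted p = 0.192 and 0.792). Markers of other cell types had deposited values for 4 of 20 leukocyte, 8 of 14 fibroblast and 5 of 14 keratinocyte and endothelial markers. These were low: the highest value in any library was 2.19 FPKM among leukocyte markers, 1.66 among fibroblast markers and 2.92 among keratinocyte and endothelial markers. The other markers have no value here. Of the 14 fibroblast markers only Pdgfrb and Postn were tested, and camera called this list lower in both clones under DMSO. Its median was -0.47 in ΔUNG (adjusted p = 0.0309; 0.246 with an estimated correlation; 0.217 with no filter; 0.0758 without ΔUNG DMSO replicate 2) and -0.62 in ΔUNG_2 (adjusted p = 0.00835; 0.204 with an estimated correlation; 0.263 with no filter). By limma neither gene was called by itself: Pdgfrb had -0.57 ± 0.20 and -0.68 ± 0.20 (adjusted p = 0.108 and 0.0697), and Postn -0.36 ± 0.15 and -0.56 ± 0.15 (adjusted p = 0.192 and 0.0540).

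**Figure D3:**
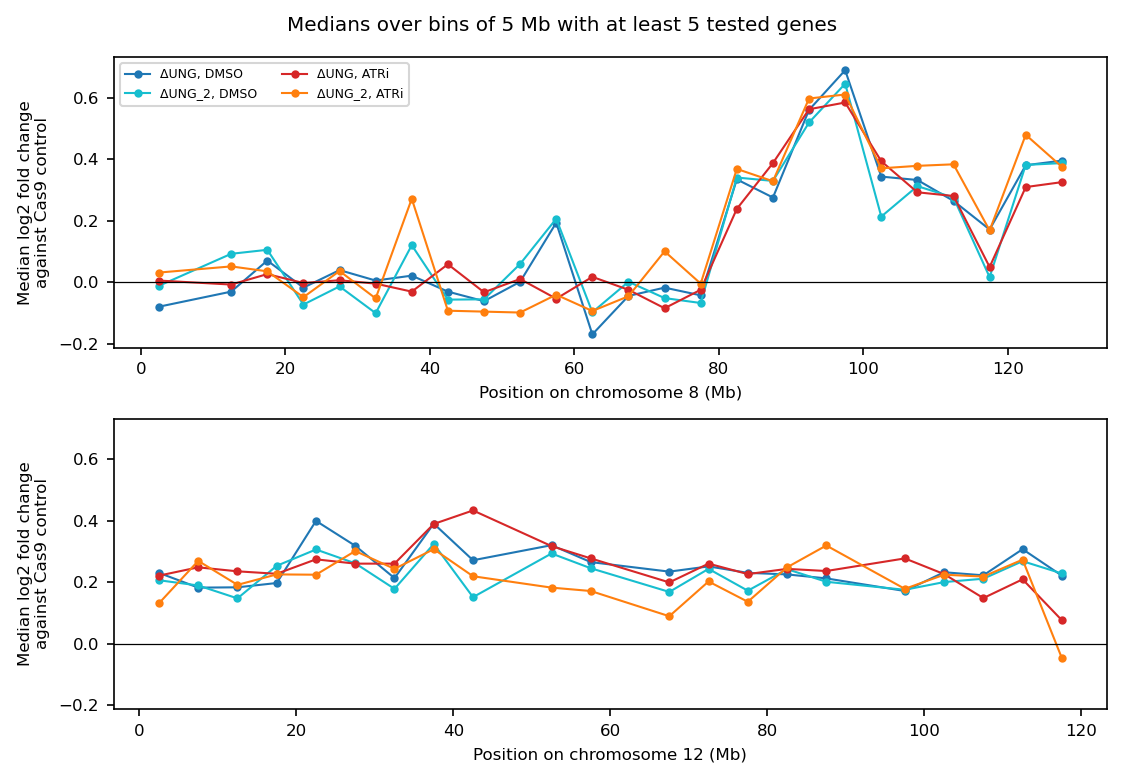
Median log2 fold change of the clones against the control in bins of 5 Mb along chromosomes 8 and 12, for DMSO and ATRi libraries; only bins with at least 5 tested genes are drawn. From 80 Mb on chromosome 8 and along chromosome 12 the medians lie mostly above 0.

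Position on the chromosome went with part of the difference between clones and control. The 436 tested genes of chromosome 12 had a median of 0.24 in ΔUNG and 0.23 in ΔUNG_2 under DMSO, and the 332 genes of chromosome 8 from 80 Mb had 0.35 and 0.34. Genes elsewhere had medians of -0.01 and -0.02. These stretches, chosen after seeing the data, held 6.8% of the tested genes and 44.4% of the genes higher in both clones, Cyba among them. Mvd and Srp54b also lie on them. Without them, 328 genes were higher and 303 lower in ΔUNG under DMSO, 267 and 356 in ΔUNG_2, and 194 and 214 in both clones. Under ATRi, 120 were then higher and 296 lower in ΔUNG, and 119 and 199 in ΔUNG_2.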

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

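Results below differed between lines in their response to ATRi by a test of the difference itself. The test of interferon-stimulated genes against the other control libraries was chosen only after the result was seen, as was the count of control lines.

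Single genes included Hap1 (-1.21) and Mvd (-1.13) in ΔUNG, and Bst2 (-1.52), Slfn9 (-1.39), Hap1 (-1.17), Rnf213 (-1.13), Dusp10 (1.20), Dcxr (0.92) and Mcam (0.77) in ΔUNG_2, as differences of log2 fold changes. Hap1 went from 17.6 to 35.4 FPKM in the control and from 31.6 to 27.1 in ΔUNG.

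The differences of both clones use the same Cas9 control libraries, so a shared sign can come from these and is not independent evidence. Some lists had a negative difference of response in both clones. They were the interferon-stimulated genes (-0.62 in ΔUNG and -0.66 in ΔUNG_2), the interferon-gamma-inducible GTPases and regulators (-0.56 and -0.73) and MHC class I antigen presentation (-0.25 and -0.34). DNA replication and E2F targets (-0.34 and -0.20), G2 and mitosis genes (-0.25 and -0.20) and replication stress and DNA damage response (-0.21 and -0.25) were also negative. So were cholesterol synthesis (-0.32 and -0.26) and glycolysis and hypoxia (-0.26 and -0.22). Positive in both were p53 target genes (0.155 and 0.32), the integrated stress response (0.11 and 0.21) and lysosome genes (0.059 and 0.15). The sign does not give the size of the response. In the control, ATRi lowered the replication, mitosis, damage response and glycolysis lists, so a negative difference there is a deeper fall. It raised the interferon, MHC class I and cholesterol lists, where a negative difference is less of a rise. The integrated stress response fell in the control, so its positive difference is less of a fall. A different level under DMSO also enters these values. Glycolysis and hypoxia genes began higher in the clones, with medians of 0.379 and 0.21 against the control. A higher start with a similar end level would give a negative difference as well. Past the threshold in ΔUNG were also nucleotide pool and thymidylate synthesis (-0.22), ribosomal proteins (-0.15) and mitochondrially encoded genes (0.42), and in ΔUNG_2 cytokines, chemokines and NF-kB targets (0.235), nucleic acid sensing (-0.083), invasive and mesenchymal melanoma genes (0.40), collagens and matrix enzymes (0.22) and fibroblast markers (0.50, over 2 genes). With an estimated correlation between genes these list calls were lost, with adjusted p of at least 0.1005 in ΔUNG and at least 0.0771 in ΔUNG_2.

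Some of these list calls were lost when a single library was left out. In ΔUNG these were nucleotide pool (without Cas9 control DMSO replicate 1, ΔUNG DMSO replicate 2 or ΔUNG ATRi replicate 2, adjusted p = 0.0849, 0.169 and 0.101) and the integrated stress response (without Cas9 control DMSO replicate 2, ΔUNG DMSO replicate 2, Cas9 control ATRi replicate 2 or ΔUNG ATRi replicate 2, adjusted p = 0.127, 0.821, 0.101 and 0.0664). Glycolysis and hypoxia in ΔUNG was lost without Cas9 control DMSO replicate 1 (-0.066, adjusted p = 0.333) or ΔUNG DMSO replicate 1 (-0.197, adjusted p = 0.0711). Lysosome genes in ΔUNG were lost without Cas9 control DMSO replicate 1, either Cas9 control ATRi replicate or ΔUNG ATRi replicate 1 (adjusted p = 0.119, 0.0574, 0.0959 and 0.0858) and turned to -0.009 without ΔUNG DMSO replicate 2. Ribosomal proteins in ΔUNG were lost without either Cas9 control DMSO replicate, ΔUNG DMSO replicate 1 or ΔUNG ATRi replicate 2 (adjusted p = 0.114, 0.0676, 0.308 and 0.750) and turned to 0.014 without Cas9 control ATRi replicate 2. In ΔUNG_2, nucleic acid sensing and fibroblast markers were lost without Cas9 control ATRi replicate 2 (adjusted p = 0.0710 and 0.0585), and collagens and matrix enzymes without Cas9 control DMSO replicate 2, ΔUNG_2 DMSO replicate 1 or Cas9 control ATRi replicate 1 (adjusted p = 0.0649, 0.0552 and 0.0570). Glycolysis and hypoxia in ΔUNG_2 was lost without Cas9 control DMSO replicate 1 (-0.019, adjusted p = 0.491), ΔUNG_2 DMSO replicate 1 (-0.208, adjusted p = 0.0775) or Cas9 control ATRi replicate 2 (-0.196, adjusted p = 0.0710).

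Other values of called lists moved by more than 1.5 times. In ΔUNG, MHC class I antigen presentation was -0.159 without Cas9 control DMSO replicate 2 and -0.402 without ΔUNG DMSO replicate 2, p53 target genes were 0.08 without ΔUNG DMSO replicate 2, G2 and mitosis genes -0.161 without ΔUNG ATRi replicate 2, and mitochondrially encoded genes 0.234 without Cas9 control ATRi replicate 2. The integrated stress response in ΔUNG was 0.333 without ΔUNG DMSO replicate 1, 0.2 without Cas9 control DMSO replicate 1, 0.182 without Cas9 control ATRi replicate 1 and 0.208 without ΔUNG ATRi replicate 1. Lysosome genes were 0.129 in ΔUNG without ΔUNG DMSO replicate 1 and 0.091 in ΔUNG_2 without Cas9 control DMSO replicate 1, and ribosomal proteins -0.245 in ΔUNG without Cas9 control ATRi replicate 1. Glycolysis and hypoxia was -0.409 in ΔUNG and -0.399 in ΔUNG_2 without Cas9 control DMSO replicate 2.

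Interferon-stimulated genes were lower in both clones under DMSO. Chance values confined to the control DMSO libraries would not carry over to the other control libraries. Under ATRi the median of the clone nearer to 0 was still -1.82, and -1.89 to -1.67 with single libraries left out. A state of the cells shared by the control DMSO and ATRi libraries would carry over, so the test cannot speak on it. Whether the difference comes from the loss of UNG or from clonal origin cannot be told apart, since the series has 1 control line.

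The same genes rose less under ATRi in both clones. By limma-voom, without the pseudocount on FPKM, the median nearer to 0 was -0.49 (-0.64 to -0.41 with single libraries left out). This covered the 37 members with a mean of at least 2 FPKM over all libraries. That mean includes the control, so members low in the clones could pass: Usp18 averaged 6.475 FPKM in the control and 0.9775 in ΔUNG_2 under DMSO. Low levels in the clones were therefore not set aside. Deeper sequencing of the control ATRi libraries would leave no difference after thinning to the smallest depth, where the median nearer to 0 was -0.65 (-0.72 to -0.50). Loss of UNG and clonal origin remain open here too, and neither was tested.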

How the results depend on the processing

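Alternatives chosen only after the data were seen were limma-voom, thinning, leaving out genes under 200 bases, setting each clone against a different control library, and leaving out chromosome 12 with chromosome 8 from 80 Mb. For the single genes and lists other than Ung in ΔUNG and the 4 results for interferon-stimulated genes given below, settings other than a left-out library gave the same direction and side of the threshold 3027 times among those set beforehand and 1332 times among those chosen later; a call was lost 281 and 15 times, gained 1 and 6 times, and the direction turned 17 and 4 times. Leaving out single libraries gave the same 1195 times, lost a call 173 times and turned the direction 42 times. Where values moved, the cause was not tested, except that a minimum fold lowers a count by construction.

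Rescaling to the same FPKM sum gave 323 genes for ΔUNG against the control under DMSO, 381 for ΔUNG_2, 223 for both clones, 2002, 2319 and 2022 for ATRi against DMSO in the control, ΔUNG and ΔUNG_2, 16 for the difference in response of ΔUNG, 276 and 183 for ΔUNG and ΔUNG_2 against the control under ATRi, and 10 between the clones. The ATRi totals split into 857 higher and 1145 lower in the control, 912 and 1407 in ΔUNG, and 983 and 1039 in ΔUNG_2. With a log2 fold change of at least 1 the counts were 118, 143, 87, 455, 593, 705, 123 and 134, in the same order without the difference in response of ΔUNG, plus 5 for the difference in response of ΔUNG_2 and 1 between the clones.

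With the libraries of the groups compared, the counts were 385 for ΔUNG under DMSO, 273 and 153 for ΔUNG and ΔUNG_2 under ATRi, 0 and 2 for the differences in response, and 0 between the clones. Without chromosome 12 and chromosome 8 from 80 Mb they were 631 for ΔUNG under DMSO, 408 for both clones, 416 and 318 under ATRi, and 0 for the difference in response of ΔUNG. limma-voom gave 1248 and 1129 under ATRi, 65 and 73 for the differences in response and 11 between the clones.

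The difference in response of ΔUNG, with 2 genes, had 7 with a pseudocount of 0.1, 10 with a pseudocount of 1, 1 with no filter, 7 with a mean of at least 2 FPKM, 7 with no intensity trend and 8 without genes under 200 bases. That of ΔUNG_2, with 8 genes, had 5 with no filter and 3 with no intensity trend. Between the clones, 5 genes became 3 with a pseudocount of 0.1, with no filter, by median ratios and after thinning, and 0 with no intensity trend. Unadjusted p under 0.05 in limma held for 1524 and 1396 genes in the differences in response and for 684 between the clones. A share of 0.05 of the 11323 genes tested would be under it without any difference. Counts of 0 stand beside the larger ones of limma-voom.

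With the replicate number as a replicate block, the counts were 4 for the difference in response of ΔUNG, 0 for that of ΔUNG_2 and 0 between the clones; the other counts stayed within 1.5 times. Libraries with the same number had correlations of their deviations from group means of -0.12 to 0.04 over 10 pairs. No large shift shared by number was thus seen across genes. Whether a number marks a shared day or passage stays open.

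The interferon-stimulated genes kept their direction in every setting, and their call in all but camera with an estimated correlation: -1.116 in ΔUNG, -1.393 in ΔUNG_2, 1.239 with ATRi in the control and -0.621 for the difference in response of ΔUNG, with adjusted p = 0.132, 0.0768, 0.108 and 0.236. Their medians ranged from -1.192 to -1.022, -1.421 to -1.317, 1.117 to 1.336 and -0.763 to -0.509 with single libraries left out, and from -1.355 to -0.905, -1.711 to -1.167, 1.154 to 1.34 and -0.675 to -0.588 in the other settings. Ung in ΔUNG, -1.026, was not called with no filter (adjusted p = 0.0546), with the libraries of the groups compared (adjusted p = 0.0681), or without Cas9 control DMSO replicate 1 or 2 or ΔUNG DMSO replicate 2 (adjusted p = 0.142, 0.0852 and 0.125), of a range from 0.00248 to 0.142, and lay between -1.311 and -0.741 with single libraries left out.

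With single libraries left out, counts ranged from 370 to 570 for ΔUNG under DMSO, 289 to 391 for ΔUNG_2, 250 to 447 for both clones, 2197 to 3006, 2752 to 3436 and 2735 to 2782 for ATRi against DMSO in the control, ΔUNG and ΔUNG_2, 0 to 7 and 0 to 10 for the differences in response, 225 to 550 and 272 to 739 under ATRi, and 0 to 5 between the clones.

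Directions turned after rescaling to the same FPKM sum for ribosomal proteins (-0.029), Mb21d1 (-0.018) and Tmem173 (-0.046) in ΔUNG under DMSO; for E2F targets (-0.05), unfolded protein response chaperones (-0.08), Tmem173 (-0.04), H2-K1 (-0.075) and Ifnar1 (-0.012) in ΔUNG_2 under DMSO; for NRF2 targets (-0.004), Cdkn1a (-0.001) and Mdm2 (-0.059) in ΔUNG and Mdm2 (-0.05) in ΔUNG_2 under ATRi; and for Ung in the control (-0.008) and H2-K1 in ΔUNG_2 (-0.02) with ATRi. The H2-K1 value also turned in the replicate block (-0.023) and after thinning (-0.035), as did the difference for Ifnar1 in ΔUNG after thinning (-0.016). Differences in ΔUNG_2 turned for Irf7 (0.157) and Cxcl10 (0.064) by limma-voom and for Cxcl10 (0.056) with a pseudocount of 0.1, and Tmem173 in ΔUNG under ATRi (0.002) by median ratios. Of these, the lists were past the threshold before.

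Directions also turned with single libraries left out, with these ranges. ΔUNG against the control under DMSO: Tmem173 -0.019 to 0.163, H2-K1 -0.042 to 0.641, Cdkn1a -0.162 to 0.012. ΔUNG_2 under DMSO: Tmem173 0 to 0.181, H2-K1 -0.202 to 0.31. ATRi against DMSO: Ung -0.048 to 0.147 and Mb21d1 -0.149 to 0.054 in the control, Ung -0.402 to 0.187 and H2-K1 -0.405 to 0.278 in ΔUNG, H2-K1 -0.01 to 0.047 in ΔUNG_2. Difference in response: lysosome genes -0.009 to 0.129, ribosomal proteins -0.245 to 0.014, Ung -0.451 to 0.138, Tmem173 -0.17 to 0.011, Ccl5 -0.308 to 0.214 and Ifnar1 -0.02 to 0.054 in ΔUNG, Cxcl10 -0.269 to 0.212 in ΔUNG_2. Under ATRi: Tmem173 -0.025 to 0.011 and Mdm2 -0.078 to 0.156 in ΔUNG; Mb21d1 -0.126 to 0.076, Tmem173 -0.03 to 0.006 and Mdm2 -0.061 to 0.174 in ΔUNG_2. Between the clones: Tmem173 -0.057 to 0.094, Irf7 -0.38 to 0.027, Isg15 -0.598 to 0.339, Cxcl10 -0.013 to 0.187, Ccl5 -0.039 to 0.088, H2-K1 -0.587 to 0.096, Mdm2 -0.053 to 0.024.

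Depth limits genes of low level, since a value of 0 in the smallest library allows 0.176 FPKM for a gene of 1 kb.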

Other observations

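Some genes known from the embryo at the stage of 2 cells rose with ATRi. Of a list of 29 genes written after the data were seen, 10 had a mean of at least 0.5 FPKM and were tested. Of these, 9 rose in the control and in ΔUNG, and 10 in ΔUNG_2, with medians of 1.94, 1.75 and 2.18. Members near 0 under DMSO could reach that mean only through their ATRi values. The filter therefore favoured members that rose, and these values do not speak for the whole list. Zscan4d went from 0.108 to 1.45 FPKM in the control. Gm2022 was listed at 0 in all DMSO libraries and at 1.26 to 3.67 FPKM under ATRi. Near-identical copies share reads, so values of single members are uncertain. Immediate early genes, also listed afterwards, rose in 11 of 15 cases in the control, 9 in ΔUNG and 11 in ΔUNG_2, with Fos at 1.72 and Junb at 1.83 in the control; with an estimated correlation camera did not call this list in any line (adjusted p = 0.0798, 0.0946 and 0.0706).

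Gm9628, named after its values were seen, was listed at 0 in all 7 knockout libraries and averaged 5.94 FPKM in the control under DMSO and 3.80 under ATRi.

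Genes of chromosome 12 and of chromosome 8 from 80 Mb were higher in both clones than in the control; the test under ATRi was chosen after the result was seen, and so were the stretches. GC content or gene length would leave no shift after their trends were removed, yet the median residual of the lower clone was 0.295 (0.287 to 0.301 with single libraries left out). Chance values confined to the control DMSO libraries are argued against by the median of 0.26 under ATRi. A state shared by the control DMSO and ATRi libraries is not addressed by that median. A candidate explanation is a difference in copy number between the control line and both clones, by which genes at each level of expression should shift: the lowest of 6 medians, over 3 equal groups of the genes by expression in each clone, was 0.23 (0.22 to 0.24). These medians use the DMSO values in which the stretches were seen to be higher. Any other shift of whole stretches would give the same, so they do not single out copy number. DNA was not measured, and neither a gain in the clones nor a loss in the control line was tested.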
